A study of Mus musculus with 7 samples.

How the data were processed

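Gene expression was measured in the colon of female CD-1 outbred mice with oligonucleotide arrays. Per the labels, colitis was induced with 6 enemas of TNBS (trinitrobenzene sulphonic acid, a hapten that provokes an immune reaction in the bowel) given in ethanol, and the control mice belonged to saline groups. No ethanol group without TNBS is among the samples, so each comparison sets TNBS with ethanol against saline. Tissue came from 4 ± 0.5 cm above the anus, RNA was taken up in TRIzol, and biotin-labelled cRNA was made from 10 µg of total RNA pooled over the mice of a group, per the labels. The 7 arrays stand for 6 RNA pools: 4 TNBS pools and 2 saline pools, of which the week 6 saline pool was hybridised on 2 arrays.

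The deposited values are signal intensities on a linear scale, 1 per probe set, which the authors made with Affymetrix Microarray Suite 5.0 and scaled on each array to a target of 150, per the labels. The 2% trimmed mean of each array was checked in the table and was 150 on all 7. Detection calls were not used here. The labels name no genome build, so no coordinates are given.

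The table held 12488 probe sets, of which 66 control probe sets were left out. The platform annotation of 2016 gave 10833 probe sets 1 gene symbol, 396 several and 1193 none, and probe sets with 1 symbol were used. Entrez identifiers of 10817 of these were found in the RefSeq gene table of the GRCm38.p6 assembly, which served for symbols alone. Each gene was represented by the probe set with the highest mean log2 value, which left 8251 genes. Values under 50 were set to 50 before taking log2, and the 2 arrays of the week 6 saline pool were averaged on the log2 scale. Genes with a value of at least 100 in the highest pool were kept, which left 4316 genes. A gene at the floor on 1 side of a comparison is given as at least so many fold higher or lower.

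Following the series' design, the week 6 TNBS pool was compared with the week 6 saline pool, and the week 8, week 10 and week 12 TNBS pools with the later saline pool. These matched comparisons have 1 pool on each side and no test, and a gene was counted when it differed at least 2-fold. The difference between both saline pools and that between both arrays of the week 6 saline pool were counted in the same way as a background. Models were fitted in R 4.3.3 with limma 3.58.1 (empirical Bayes with an intensity trend, two-sided). The pooled model compared the 4 TNBS pools with the 2 saline pools with the control set as a covariate and 3 residual degrees of freedom. The late model compared the 3 later TNBS pools with the later saline pool, and the interaction term compared the TNBS effect at week 6 with the later effect, each with 2 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the 4316 genes, or over the 21 tested lists, with a threshold of 0.05. There are no replicate pools within a group, so these p-values measure the spread between pools and not between mice. TNBS pools of different times count as replicates in these models, so change over time is part of that spread. In the late model the lone saline pool is assumed to vary like the later TNBS pools.

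The groups of genes were 25 lists. They covered neutrophil and acute inflammation, chemokines, macrophage and monocyte, T and NK lymphocyte, B and plasma cell, MHC class II and antigen presentation, interferon response, complement and acute phase, and mast cell and eosinophil genes. They also covered collagens and fibrillar matrix, matrix proteases and inhibitors, fibrogenic growth factors and TGF-beta targets, smooth muscle, absorptive colonocyte, goblet and secretory epithelium, proliferation, and mitochondrial respiration and fatty acid oxidation genes. Drug and xenobiotic metabolism, endothelium, enteric neuron and glia, adipose tissue, stress and heat shock, and 3 lists for other tissues (skeletal muscle, squamous epithelium, pancreas) completed them. Of 629 list symbols, 534 were on the array, 2 of them through an older name. A list was tested when at least 5 members passed the filter, which held for 21 of the 25. In each matched comparison the list's median log2 difference was placed among 10000 random lists of equal size drawn from 20 bins of mean expression, and percentiles of 97.5 and above or 2.5 and below were counted. On the pooled and interaction terms the lists were tested with limma's camera at its preset correlation of 0.01, and again with the correlation estimated from the data.

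Genes are named by a rule. Rik, Gm and EST symbols were left out. At week 6 the 12 genes with the largest differences upward and the 12 downward, among genes above the floor on every array of the comparison, are named, and 10 and 10 in each later comparison. For the pooled model the 10 rises and 10 falls with the smallest p and 1 direction in all 4 comparisons are named, and for each list up to 4 members with the largest absolute change. Genes named outside the rule are said to have been chosen after their values were seen. The lists, the rule, the floor, the filter, the comparisons and the alternatives listed next were chosen before the data were examined.

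Alternatives were floors of 25 and 100, log2(value + 50), quantile normalization, equal array medians, the mean of a gene's probe sets, a 3-fold limit, no filter or a filter at 300, no intensity trend, no covariate for the control set, the saline arrays as separate samples, the other saline pool as the control, and leaving out each array or pool. Others, added after seeing the data, are named with their effect in the closing section. The models were tested on simulated data with 200 of 4316 genes changed, in 10 simulations. The pooled model recovered 51.5% of genes changed 2-fold and 88.5% of genes changed 4-fold, with 6.4 false calls per simulation. The late model recovered 2.8% and 52.7%, and the interaction term recovered 0% of both sizes. A list shifted in the simulation was found in 10 of 10 simulations on the pooled and on the interaction term, at the preset correlation. The estimated correlation was not tried on simulated data. Lists that had not been shifted were called 0.3 times per simulation on the interaction and 0 times on the pooled term. The simulated genes varied independently of each other. In the data the correlation estimated within lists ranged from -0.02 to 0.63, so the simulated rates of list calls cannot be carried over to the data. The number of arrays limits the precision of every value.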

Results

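Colon RNA was compared at 4 times after repeated TNBS enemas, a mouse model of colitis, with colon RNA of saline controls. The week 6 TNBS pool held RNA of 6 mice killed 3 days after the last of 6 enemas. The week 8 pool held RNA of 4 mice killed at 2 weeks, the week 10 pool of 5 mice at 4 weeks, and the week 12 pool of 4 mice at 6 weeks after the enemas. The week 6 saline pool came from 5 mice and was measured on 2 arrays. The later saline pool came from 4 mice, 2 killed at week 8 and 2 at week 10, so week 12 had no control of its own age. Each group was a single pool, and there are no replicates of any group beyond the repeated array.

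The median signal of the arrays was between 51.8 and 61.2, and 45.4% to 49.2% of probe sets lay under the floor of 50. Across probe sets, which are not independent replicates, the log2 values of both week 6 saline arrays had r = 0.987. The week 8 TNBS array had r between 0.952 and 0.971 with the other arrays, and the remaining pairs lay between 0.960 and 0.981. The ratio of the 3' to the 5' probe set of beta-actin, a measure of RNA integrity and labelling, was 1.14 to 1.24 on the 3 week 6 arrays. It was 0.798 to 0.818 on the 4 later arrays. The same ratio of Gapdh did not separate the arrays, at 0.912 to 0.942 at week 6 and 0.869 to 1.00 later.

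The first comparison asks which transcripts differ in the colon 3 days after the last enema. At week 6 Mcpt2 and Mcpt1, chymases of mucosal mast cells, were 16.0-fold and 11.7-fold higher in the TNBS pool than in the week 6 saline pool. Reg3b, a secreted epithelial lectin that binds bacteria, was 12.6-fold higher, with a signal of 2095 against 162 and 170 on the saline arrays. Pla2g2a, a secreted phospholipase with antibacterial activity, was 8.55-fold higher. Ubd, a ubiquitin-like modifier induced by interferon gamma, was 5.50-fold higher, and Iigp1, an interferon-inducible GTPase, was 4.54-fold higher.

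Reg1, a regenerating lectin, was 6.66-fold higher, Anxa8, an annexin, 6.58-fold higher, Plet1, a surface protein of epithelial progenitors, 4.59-fold higher, and Wfdc18, a secreted protein with a protease inhibitor fold, 4.24-fold higher. Both pancreatic enzyme genes among the most changed genes, Ctrb1 (chymotrypsinogen) and Cel (carboxyl ester lipase), were 10.6-fold and 5.30-fold higher. The genes lowest against saline included the actin-severing proteins Scin and Gsn, at 3.33-fold and 2.47-fold lower. Capn9, a calpain of the digestive tract, was 3.18-fold lower, Nbl1, an antagonist of bone morphogenetic proteins, 3.17-fold lower, and Slc20a1, a phosphate transporter, 3.06-fold lower. Rnps1, an RNA-binding splicing factor, was 2.96-fold lower, Eif2ak1, a haem-regulated kinase, 2.68-fold lower, and Frat2, a Wnt pathway protein, 2.66-fold lower. Gabarapl1, an autophagy protein, was 2.47-fold lower and Pck1, an enzyme of gluconeogenesis, 2.28-fold lower. The immunoglobulin segments Igkv9-120 and Ighv1-54, whose probe sets share sequence with other genes, were 2.62-fold and 2.28-fold lower. Igkv9-120 read 901 and 927 on the week 6 saline arrays, 349 in the week 6 TNBS pool and 373 in the later saline pool. Ighv1-54 read 835 and 941, 389 and 506. Both were thus also low in the later saline pool, without TNBS. With the mean of probe sets Scin (log2 -0.87), Frat2 (-0.92) and Igkv9-120 (-0.46) were less than 2-fold lower, with the other probe sets of Scin and Igkv9-120 at the floor. Reg1, whose other probe set also lay at the floor, was at 1.37.

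Groups of immune genes were higher together at week 6. In the neutrophil and acute inflammation list 5 of 9 genes were at least 2-fold higher, with a median log2 difference of at least 1.44. These 5 lay under the floor in saline and passed the filter through the week 6 TNBS pool alone. The filter thus fixed their rise at 2-fold or more. The 4 genes that averaged at least 100 in saline had log2 differences between -0.15 and 0.10. Of the list, 27 genes were on the array. The median gene, Il1b, lay under the floor in saline, so the median was 2.44 with a floor of 25 and 0.44 with a floor of 100. Cxcl5, a neutrophil-attracting chemokine, was at least 6.64-fold higher, Saa3 at least 5.24-fold, and S100a8 and S100a9, the subunits of calprotectin, at least 4.03-fold and 3.18-fold. Of the interferon response list, 9 of 16 genes were at least 2-fold higher (median 1.26), with Igtp 3.92-fold, Ifi47 3.16-fold and Irgm1 at least 2.89-fold higher. The later saline pool, without TNBS, was also above the week 6 saline pool on this list, by a median log2 of 0.96. Ifit1, Isg15 and Rsad2 read 134, 302 and 62.3 in the week 6 TNBS pool but 256, 695 and 170 in the later saline pool. Gbp2, Iigp1 and Igtp went the other way, with 921, 386 and 304 against 433, 145 and 124. The rise at week 6 thus depended in part on the saline pool used. Of the macrophage list, 5 of 11 were at least 2-fold higher (median 0.95), with Tyrobp 4.22-fold, Arg1 at least 3.40-fold, Lyz2 2.15-fold and C1qb 2.14-fold higher. Of 8 chemokine genes, 4 were (median 0.92), with Ccl8 at least 4.74-fold, Ccl9 2.51-fold and Cxcl9 at least 2.46-fold higher. Ccl8, Cxcl13 and Cxcl9 averaged under 100 in saline and passed the filter through TNBS pools alone. The 5 chemokine genes that averaged at least 100 in saline had log2 differences of -0.30 (Ccl22), -0.04 (Cx3cl1), 0.13 (Ccl6), 0.71 (Cxcl12) and 1.33 (Ccl9). The antigen presentation list had a median of 0.48, with Psmb9 2.45-fold, Tap1 2.10-fold and H2-Oa 2.02-fold higher. Arg1, Cxcl9 and H2-Oa passed the filter through the week 6 TNBS pool alone. Complement genes had a median of 0.45, with Cd55 1.85-fold higher. The B and plasma cell list had a median of 0.33 with members on both sides, Ms4a1 2.11-fold higher and Ighm 1.66-fold lower.

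The proliferation list had 20 of 21 genes above 0 (median 0.55), with Mki67 2.57-fold, Birc5 2.41-fold, Top2a 2.00-fold and Pcna 1.82-fold higher. The collagen list had 20 of 24 genes above 0 (median 0.34), with Col5a2 2.31-fold, Sparc 1.95-fold and Col4a1 1.82-fold higher. The adipose list had a median of 0.73, with Scd1 1.91-fold and Adipoq at least 1.82-fold higher and Pck1 lower. The pancreas list had a median of 2.40 and 6 of 9 genes at least 2-fold higher. Prss2, a trypsinogen, was at least 22.5-fold higher and Reg2 at least 5.80-fold. The absorptive colonocyte list had 18 of 23 genes below 0 (median -0.25), with Fabp2, a fatty acid carrier, 2.23-fold lower, Car4, a carbonic anhydrase, 2.02-fold lower and Aqp8, a water channel, 1.55-fold lower. The drug metabolism list had a median of -0.29, with Sult1a1 2.19-fold, Abcb1a 1.89-fold and Gstm1 1.67-fold lower. These 13 lists lay at percentile 97.5 or above, or 2.5 or below, among random lists. Without the first saline array the B cell (0.12), colonocyte (-0.16) and drug metabolism (-0.25) medians lay inside, and without the second the drug metabolism median (-0.20) did. With a floor of 100 the adipose median was 0 at percentile 58.8 and the colonocyte median -0.13 at 12.1, both inside. The interferon (0.56), chemokine (0.46) and pancreas (1.54) medians were then smaller but outside. With the mean of probe sets the B cell (0.11), colonocyte (-0.16) and complement (0.29) medians lay inside.

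The other lists lay between these percentiles at week 6. The matrix protease list had a median of 0.17, although Mmp12, a macrophage elastase, was at least 6.35-fold higher, Timp1 3.37-fold and Plat 2.47-fold. Mmp12 and Plat passed the filter through TNBS pools alone, and Timp1 differed between the saline arrays, at 69.8 and 286.5. With the mean of probe sets the matrix protease median was 0.52 at percentile 98.3, outside the random lists. The enteric neuron list lay outside with a floor of 100 (-0.30) and under log2(value + 50) (-0.26), and the stress list without the second saline array (0.14). Medians were -0.04 for fibrogenic factors, -0.17 for smooth muscle, -0.07 for goblet cell genes, -0.15 for mitochondrial genes, -0.30 for enteric neuron and glia, 0.19 for squamous epithelium and 0.12 for stress genes. Lists with fewer than 5 measured genes had medians of 2.05 (mast cell), 0.91 (endothelium), 0.28 (skeletal muscle) and 0.24 (T and NK lymphocyte). Of the 4 mast cell genes 2 were at least 2-fold higher, while Tpsb2, a tryptase, was 1.47-fold higher and Kit, the receptor for stem cell factor, 1.45-fold lower. In the endothelium list Vcam1, an adhesion molecule for leukocytes, was 2.43-fold higher and Madcam1, an endothelial ligand for the gut homing integrin of leukocytes, 1.88-fold higher.

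Of 4316 genes, 110 were at least 2-fold higher and 43 at least 2-fold lower at week 6. Of these, 35 and 6 were at least 3-fold different. By the same rule, both arrays of the week 6 saline pool differed in 21 genes in each direction, with an SD of the log2 difference of 0.29.

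**Figure D1:**
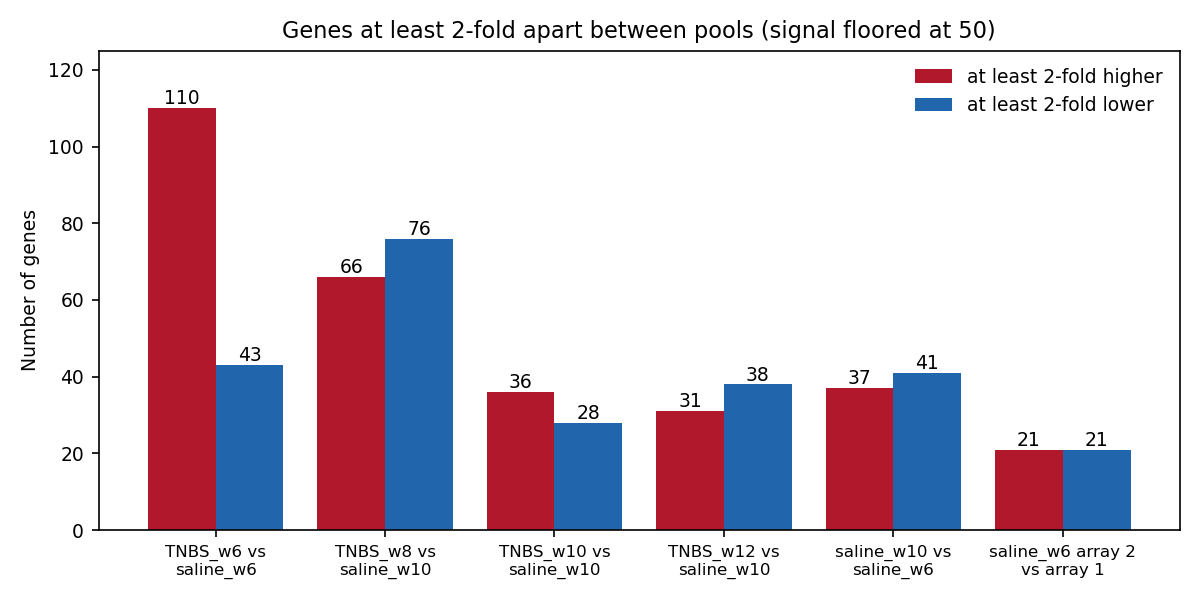
Number of genes (vertical axis) at least 2-fold higher or lower (bars) in the 4 matched comparisons, in the later saline pool against the week 6 saline pool, and in the second against the first array of the week 6 saline pool. The week 6 comparison has 110 higher and 43 lower genes, and the repeated arrays have 21 and 21.

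The second comparison addresses the colon 2 weeks after the enemas. At week 8 Mcpt1 was 12.9-fold, Mcpt2 7.97-fold and Cma2, a further mast cell chymase, 4.82-fold higher in the TNBS pool than in the later saline pool, and Reg3b was 10.5-fold and Reg1 5.77-fold higher. Pancreatic digestive enzymes filled most of the other places: Cela2a, an elastase, was 12.0-fold, Prss2 11.6-fold, Ctrb1 6.48-fold and Cel 5.28-fold higher. Rpl41, a ribosomal protein gene, was 4.15-fold higher, but its signal of 4600 lay below the 9879 and 11414 of the week 6 saline arrays.

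The genes lowest against saline at week 8 were led by Tgm3, a transglutaminase that cross-links epithelial proteins, at 4.06-fold. Edn1, the precursor of the vasoconstrictor endothelin 1, was 2.52-fold lower. Slc26a2, a sulphate transporter, was 3.00-fold lower, Slc34a2, a phosphate transporter, 2.88-fold lower, and Sult1a1, a sulphotransferase, 2.62-fold lower. Pus1, a pseudouridine synthase, was 3.33-fold lower, Gdpd3, a phosphodiesterase, 3.06-fold, Acvr2b, an activin receptor, 2.99-fold, Tbc1d10a 2.76-fold and Xpnpep1, an aminopeptidase, 2.58-fold. A second probe set of Tbc1d10a had a log2 difference of -0.12 and that of Sult1a1 lay at the floor, so with the mean of probe sets they were at -0.79 and -0.69, and Reg1 was at 1.26. At a floor of 100, Slc34a2 (-0.96), Pus1 (-0.90), Tbc1d10a (-0.83), Acvr2b (-0.70) and Edn1 (-0.66) were under 2-fold.

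At week 8, 5 lists lay outside the random lists. The pancreas list had a median log2 difference of 2.70 with 8 of 9 genes at least 2-fold higher, among them Reg2 at least 16.5-fold and Pnliprp1 at least 7.31-fold. The goblet and secretory epithelium list had a median of 0.52. Reg3b, Reg1, Reg3g (2.94-fold) and Agr2 (2.13-fold), a disulphide isomerase needed for mucin production, were its genes at least 2-fold higher. The interferon list had a median of 0.50, with Ifit1 2.35-fold, Ifit2 1.99-fold and Usp18 1.98-fold higher. In the drug metabolism list 6 of 16 genes were at least 2-fold lower (median -0.69), with Ces1d at least 2.73-fold, Gstm2 2.36-fold and Cyp3a13, a cytochrome P450, 2.23-fold lower. The mitochondrial list had a median of -0.15, with Acaa2 1.70-fold and Cox4i1 1.56-fold lower and Cox7a2 1.46-fold higher. Medians were 0.00 for neutrophil, 0.17 for macrophage and 0.16 for chemokine genes. The chemokine list lay outside with a floor of 25 (0.36, percentile 99.6) and with the mean of probe sets (0.36, percentile 99.3), and under log2(value + 50) (0.26). With the mean of probe sets the B cell (0.33) and collagen (0.19) lists lay outside too, the latter also with a floor of 100 (0.11), while the mitochondrial list lay inside (-0.049).

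In all, 66 genes were at least 2-fold higher and 76 at least 2-fold lower at week 8. With equal array medians the split was 116 and 32, with quantile normalization it was 76 and 46, and the mitochondrial median was 0.029 with the former, which shifts all genes alike and left the list outside at percentile 2.32, and inside random lists with the latter (-0.18). Equal medians moved the median gene by 0.18 at week 8, 0.14 at week 10 and 0.06 at week 12 on the log2 scale, and against the week 6 saline pool the goblet median was -0.052, while the adipose (1.40), stress (0.36) and proliferation (0.29) medians lay outside.

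The third comparison addresses the colon 4 weeks after the enemas. At week 10 Reg3b was 12.0-fold higher in the TNBS pool than in the later saline pool, with a signal of 4589 against 382. Reg3g, a lectin that kills Gram-positive bacteria, was 3.68-fold higher, and Mcpt1 and Mcpt2 were 4.2-fold and 4.18-fold higher. A second probe set of Mcpt1 had a signal of 56.9 at week 10 against saline under the floor, a log2 difference of at least 0.19, and the mean of its probe sets was 1.13. A second probe set of Reg3g lay at the floor in both pools, which gave a mean of 0.94. Ubd was 4.39-fold and Iigp1 2.32-fold higher. Ocln, a protein of tight junctions, was 2.81-fold higher.

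Sinhcaf, a subunit of a histone deacetylase complex, was 2.43-fold higher and Vps54, of a vesicle tethering complex, 2.30-fold higher. Igfbp4, which binds insulin-like growth factors, was 2.31-fold higher on its chosen probe set, while another probe set of the gene had a log2 difference of -0.25. Lgals3bp, a secreted ligand of galectin 3, was 2.67-fold lower, H2-M9, a class I MHC gene, 2.65-fold, Nsmf 2.54-fold and the immunoglobulin segment Igkv15-103 2.35-fold. Ehf, an epithelial transcription factor, was 2.33-fold lower, Wdfy2 2.29-fold, Krt32, a keratin, 2.27-fold, Adk (adenosine kinase) 2.26-fold, Apob, the apolipoprotein of chylomicrons, 2.23-fold, and Dbnl, an actin-binding adaptor, 2.23-fold. Other probe sets of Nsmf, Wdfy2, Krt32 and Adk lay at the floor, and with the mean of probe sets these genes were at -0.67, -0.60, -0.59 and -0.39, Igkv15-103 at -0.89 and Igfbp4 at 0.32, all under 2-fold. Raising the floor to 100 put Igkv15-103 (-0.92), Nsmf (-0.87), H2-M9 (-0.76), Wdfy2 (-0.72), Apob (-0.29) and Krt32 (-0.28) under 2-fold.

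At week 10, 4 lists lay outside the random lists. In the proliferation list 17 of 21 genes lay below 0 (median -0.34), with Ccne1 and Mcm5 1.79-fold, Birc5 1.69-fold and Tk1 1.64-fold lower. In the absorptive colonocyte list 21 of 23 genes lay below 0 (median -0.19), with Cdh1 (E-cadherin) 1.72-fold and Mep1a, a brush border protease, 1.70-fold lower. The squamous epithelium list had a median of -0.47, with Lor 1.95-fold and Krt4 1.76-fold lower. The complement list had a median of 0.26 at percentile 97.5, with C1ra 1.39-fold higher and Hp 1.56-fold lower. With a floor of 100 the squamous median was -0.081 at percentile 20.3 and the complement median 0.00072 at 64.7, both inside. The complement median also lay inside with equal array medians (0.39) and under log2(value + 50) (0.16), and the squamous median with quantile normalization (-0.36) and under log2(value + 50) (-0.31). The drug metabolism list (median -0.19) lay inside here but outside with floors of 25 and 100 (-0.19 each), quantile normalization (-0.19), equal medians (-0.055) and under log2(value + 50) (-0.15). The chemokine list lay outside with a floor of 25 (0.30) and under log2(value + 50) (0.22), the goblet list under the latter (-0.17), the antigen presentation list with quantile normalization (0.19) and the collagen list with the mean of probe sets (0.14). The interferon median was 0.04 and the pancreas median -0.11.

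At week 10, 36 genes were at least 2-fold higher and 28 at least 2-fold lower, and the split was 66 and 17 with equal array medians. Against the week 6 saline pool, the complement median turned to -0.25 and the colonocyte median to 0.13. The interferon (1.07), adipose (0.86), antigen presentation (0.24), collagen (-0.22), goblet (-0.22) and enteric neuron (-0.56) medians then lay outside.

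The fourth comparison addresses the colon 6 weeks after the enemas, against the later saline pool. At week 12 Ctse, an aspartic protease of the gastrointestinal epithelium, was 3.07-fold higher, Cd53, a tetraspanin of leukocytes, 2.60-fold, and Ccr6, a chemokine receptor of lymphocytes and dendritic cells, 2.39-fold. Edn1 was 2.55-fold higher. Pla2g2a was 7.08-fold lower, with a signal of 82.9 against 587. Mcpt1, Mcpt2 and Reg3b, higher at weeks 6, 8 and 10, were at least 1.48-fold, at least 1.44-fold and 1.90-fold lower.

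Limk1, a kinase of actin dynamics, was 2.54-fold higher, Prkar2a, a subunit of protein kinase A, 2.43-fold, Oser1 2.33-fold, Gstm2, a glutathione transferase, 2.21-fold, and Pgap2 and Cand1 2.19-fold. Ctrb1 was 2.93-fold lower, Vps51, of a vesicle tethering complex, 2.61-fold, Hsd3b7, an enzyme of bile acid synthesis, 2.53-fold, and St3gal4, a sialyltransferase, 2.53-fold. Isg15 and Usp18, both induced by type I interferon, were 2.60-fold and 2.5-fold lower. Pcp4l1 was 2.47-fold, Cyp3a13 2.39-fold and H2-D4 2.37-fold lower. With the mean of probe sets Limk1 (log2 0.67), Gstm2 (0.81) and H2-D4 (-0.62) were under 2-fold, with other probe sets of Limk1 and H2-D4 at the floor. At a floor of 100, Prkar2a (0.72), Ccr6 (0.62), Limk1 (0.60), Usp18 (-0.51), Vps51 (-0.47), Pcp4l1 (-0.45) and St3gal4 (-0.39) were.

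At week 12, 9 lists lay outside the random lists, all with medians below 0. The interferon list had 14 of 16 genes below 0 (median -0.48), with Ifit2 at least 3.72-fold and Ifit1 2.15-fold lower. The goblet list had 15 of 16 genes below 0 (median -0.41), with Sst 1.85-fold, Pigr, the transporter of secretory IgA, 1.5-fold and Zg16, a mucus lectin, 1.42-fold lower. The smooth muscle list had 12 of 13 below 0 (median -0.40), with Des (desmin) 1.59-fold and Actg2 1.5-fold lower and Tpm2 1.53-fold higher. All 6 genes of the enteric neuron and glia list lay below 0 (median -0.43), with Sox10, a glial transcription factor, 1.77-fold and Tubb3, a neuronal tubulin, 1.59-fold lower. The adipose median was -0.71, with Adipoq at least 2.69-fold and Lep 2.06-fold lower, and the pancreas median was -0.61. Smaller medians were those of the colonocyte (-0.24), stress (-0.19) and collagen (-0.18) lists, with Mep1b 1.62-fold, Ier3 1.66-fold and Lamb1 1.79-fold lower. The largest change in the colonocyte list went the other way, with Slc4a4 1.63-fold higher. With a floor of 100, 5 of these lists lay inside the random lists, with medians of -0.13 (adipose, percentile 13.2), 0 (pancreas, 50.9), -0.12 (enteric neuron, 10.6), -0.074 (collagen, 4.89) and -0.15 (stress, 2.71). With the mean of probe sets the stress median (-0.093) lay inside.

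At week 12, 31 genes were at least 2-fold higher and 38 at least 2-fold lower, against 41 and 33 with equal array medians. Against the week 6 saline pool several directions turned: the medians of the interferon, colonocyte and stress lists were 0.29, 0.057 and 0.084, the adipose and pancreas medians of -0.12 and 0 lay inside, that of complement (-0.53) outside, and the log2 differences of Limk1, Isg15 and Usp18 were -1.27, 0.53 and at least 0.19.

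**Figure D2:**
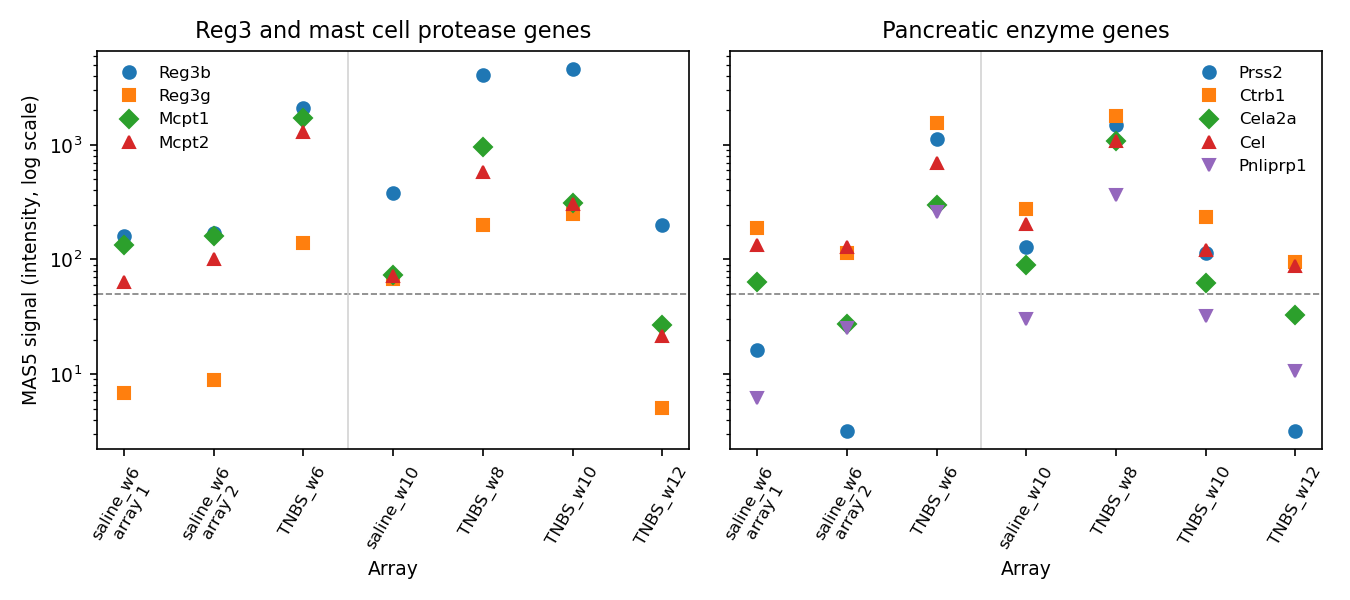
MAS5 signal (vertical axis, log scale) on each of the 7 arrays (horizontal axis) of Reg3b, Reg3g, Mcpt1 and Mcpt2 in 1 panel and of 5 pancreatic enzyme genes in the other, with a dashed line at the floor of 50 and a grey line between the week 6 arrays and the later arrays. Reg3b reads 2095, 4017 and 4589 in the week 6, week 8 and week 10 TNBS pools and 201 in the week 12 pool, while Ctrb1 reads 1543, 1790, 236 and 94.4.

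The background between controls was of similar size to the week 10 and week 12 comparisons. The later saline pool had 37 genes at least 2-fold higher and 41 at least 2-fold lower than the week 6 saline pool. Against single arrays of the latter, 49 and 50 or 55 and 64 were. Its interferon list was higher by a median log2 of 0.96 and its drug metabolism list by 0.29. The fibrogenic factor, complement and collagen lists had medians of -0.40, -0.35 and -0.28. All these lists lay outside the random lists, although neither pool had TNBS, and the other tested lists lay inside.

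Across all 4 TNBS pools, Cd53 had the smallest p in limma's pooled model, with a log2 difference of 1.51 ± 0.19 (SE, 6 pools) and an adjusted p of 0.166. It was 3.49-fold, 2.63-fold, 2.22-fold and 2.60-fold higher at weeks 6, 8, 10 and 12. The next genes with higher values were Arih1, a ubiquitin ligase (log2 0.97, adjusted p = 0.457), Bzw2 (0.85), Chordc1, a co-chaperone (0.67), Chrne, an acetylcholine receptor subunit (0.87), and Gatm, of creatine synthesis (0.70). Il18bp, which neutralises interleukin 18, had 0.95, Cnpy2 0.54, Cytip, a leukocyte adaptor, 0.54 and Arfgef1 0.51. Lower values were those of Rnps1 (-1.0), Cyp3a13 (-0.87), Adk (-0.86), Hand1, a transcription factor (-0.81), and Tmem14c (-0.73). Mrps34, a mitochondrial ribosomal protein, had -0.71, Ndufa8, of respiratory complex I, -0.63, Kcnk1, a potassium channel, -0.60, Tubb3 -0.58 and Rnf167 -0.57. Adjusted p was 0.887 for the 18 genes after Arih1. Some of these genes differed between the week 6 saline arrays. Arih1 read 522.3 and 193.5 there against 618.8 in the week 6 TNBS pool, and Cd53 153.2 and 78.5 against 382.5. Chrne read 202.6 and 70.1 against 194.1, so its direction at week 6 depended on the saline array.

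No gene of the 4316 passed the threshold in limma's pooled model, where 220 had an unadjusted p under 0.05 against 215.8 given by chance. Adjusted over the list alone, 1 gene passed, Tubb3 of the enteric neuron and glia list. Its chosen probe set, 1 of 2 for the gene, is marked for sequence shared with other genes. The late model gave 0 genes, with 79 at an unadjusted p under 0.05, also against 215.8 given by chance. Without the week 12 pool the pooled model gave 2 genes.

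Of the 21 lists tested on the pooled model, 7 rose and 3 fell, and none of these calls held with an estimated correlation. For the enteric neuron list the estimated correlation was 0.016, near the preset 0.01. Its unadjusted p in camera still went from 0.014 to 0.093. Loss of a call in that version thus need not reflect correlation between genes. The macrophage list rose by a median log2 of 0.44 with 10 of 11 genes above 0 (adjusted p = 0.0002; adjusted p = 0.458 with an estimated correlation). The pancreas list rose by 1.40 with 9 of 9 genes above 0 (adjusted p = 0.001; 0.458 adjusted p with an estimated correlation). The antigen presentation list rose by 0.25 (14 of 16 genes, adjusted p = 0.0029) and the chemokine list by 0.48 (7 of 8, adjusted p = 0.0044), each with an adjusted p of 0.458 with an estimated correlation. The interferon list rose by 0.50 (12 of 16, adjusted p = 0.0029), the collagen list by 0.13 (17 of 24, adjusted p = 0.0091) and the neutrophil list by 0.57 (6 of 9, adjusted p = 0.037). For these 3 lists the adjusted p was 0.557 with an estimated correlation. Of the 9 neutrophil genes, 5 had passed the filter through the week 6 TNBS pool alone. Ccl8, Cxcl13 and Cxcl9 of the chemokine list had passed it through TNBS pools alone.

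The drug metabolism list fell by 0.28 with 1 of 16 genes above 0 (adjusted p = 0.0029), and the absorptive colonocyte list fell by 0.21 with 2 of 23 above 0 (adjusted p = 0.0032). The enteric neuron and glia list fell by 0.32 with 1 of 6 above 0 (adjusted p = 0.032). The adjusted p of these 3 lists was 0.458 with an estimated correlation. The goblet list had a median of -0.09 but a mean of 0.23 and an upward test direction, and the adipose list a median of 0.07 and a downward test direction, both short of the threshold. Without the week 6 TNBS pool, or without the week 6 saline pool, 0 lists passed the threshold in limma's camera (smallest adjusted p 0.0691 and 0.0740), and the interferon median was -0.011. The neutrophil and interferon lists fell short of the threshold without the week 8 pool (adjusted p = 0.0667 each), and the enteric neuron list without the later saline pool (0.270) or the week 12 pool (0.100).

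Other settings also ended or added pooled calls in camera. The neutrophil list fell short with a floor of 25 (adjusted p = 0.0620), a floor of 100 (0.0872, median 0.19), equal medians (0.0829) and no filter on low genes (0.254, median 0). The enteric neuron list did so with quantile normalization (0.0518) and no filter (0.220). Without the control-set covariate the neutrophil and collagen lists (0.553 each), the colonocyte list (0.181) and the drug metabolism list (0.0773) did. The smooth muscle list passed downward with quantile normalization (0.0368), a filter at 300 (0.0292) and without the week 8 pool (0.0146). The complement list passed upward with a floor of 100 (0.0297), quantile normalization (0.0345), without the later saline pool (0.0164) and without the week 12 pool (0.0390). The proliferation list passed upward without probe sets of shared sequence (0.0275), without the later saline pool (1.45e-06) and without the week 10 pool (0.00533). The matrix protease list did so without the later saline pool (0.0278) and the goblet list without the week 12 pool (0.0360).

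**Figure D3:**
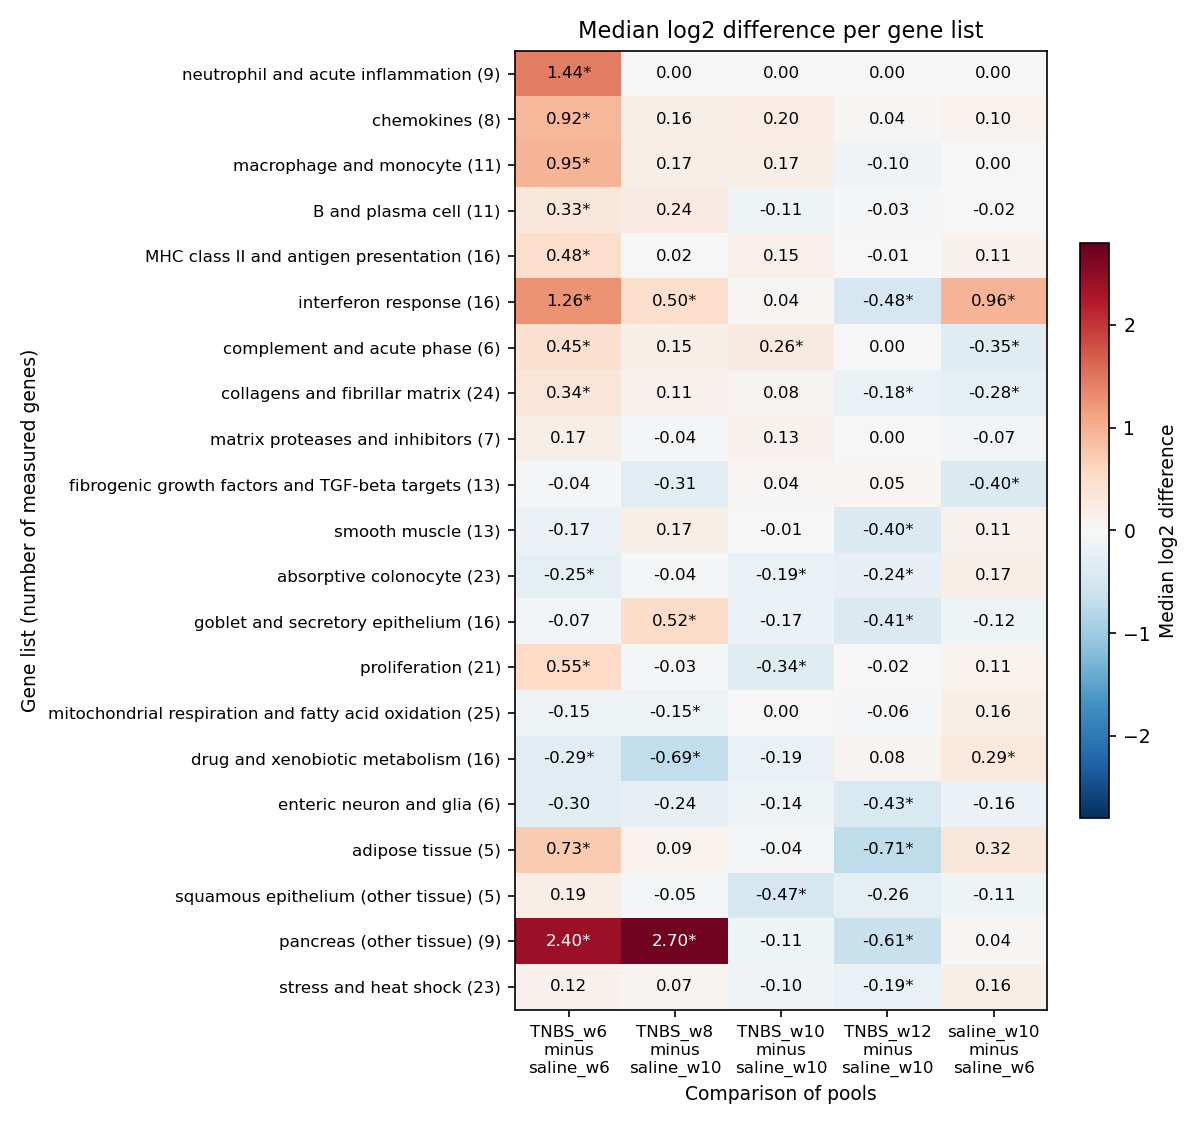
Median log2 difference (colour) of the 21 lists with at least 5 measured genes (vertical axis, number of genes in brackets) in the 4 matched comparisons and in the later saline pool against the week 6 saline pool (horizontal axis), with a star at percentile 97.5 or above or 2.5 or below among random lists. The week 6 comparison has 13 starred lists, and weeks 8, 10 and 12 have 5, 4 and 9. Between the saline pools the interferon, complement, collagen, fibrogenic factor and drug metabolism lists are starred too.

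Whether the TNBS effect at week 6 differed from the later effect was tested with the interaction term. No gene passed in limma, with 80 at an unadjusted p under 0.05 and a smallest adjusted p of 0.999. Week 6 has 1 TNBS pool and 1 saline pool, so the spread in this test comes from the 3 later TNBS pools alone. Of the 21 lists, 8 rose more at week 6 than later in camera at the preset correlation. The neutrophil list differed by a median log2 of at least 1.44, the interferon list by 1.21, the proliferation list by 0.68, the chemokine list by 0.67 and the macrophage list by 0.55. The antigen presentation list differed by 0.46, the collagen list by 0.35 and the matrix protease list by 0.32. Short of the threshold, the goblet list had a median of 0.04 but a downward test direction, and the drug metabolism list a median of -0.09, a mean of 0.02 and a downward direction. None of the 8 calls held with an estimated correlation, where the adjusted p was 0.394 at the smallest (adjusted p between 0.394 and 0.500 with an estimated correlation). With 2 residual degrees of freedom, and with that version untried on simulated data, this loss does not decide whether a list differed. In the chemokine list Ccl8, Cxcl13 and Cxcl9 passed the filter through TNBS pools alone. In the neutrophil list 5 of 9 genes passed the filter through the week 6 TNBS pool alone. Of these, 4 lay at the floor in all later pools and so had no residual variance. With the 8 such genes of the 4316 left out, an alternative added after seeing the data, the neutrophil median was 0.18 and its call was lost (adjusted p = 0.158), while the other 7 lists passed. At the preset correlation, calls were lost with a floor of 100 for the chemokine (adjusted p = 0.0647), interferon (0.0717) and matrix protease (0.0879) lists. Without a filter on low genes they were lost for the chemokine and interferon (0.216 each), antigen presentation (0.132) and collagen (0.261) lists. The matrix protease list also fell short with a floor of 25 (0.0647), a filter at 300 (0.0640) and without the week 8 pool (0.0971), and the collagen list without the week 12 pool (0.0696). Calls were gained upward with a floor of 100 for the complement (0.00476) and squamous epithelium (0.0249) lists. Without the week 8 pool they were gained upward for the pancreas (2.15e-07), stress (0.00572) and complement (0.0472) lists, and without the week 12 pool downward for smooth muscle (0.0417).

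Persistence was read from genes that differed at week 6 and again later, in comparisons that share no array. Of the 110 genes at least 2-fold higher at week 6, 23 were so at week 8, where 1.68 would be shared by chance if genes were independent. Of these 23, 6 belong to the pancreas list (Cel, Cela2a, Ctrb1, Pnliprp1, Prss2 and Reg2), and Reg1 is also expressed in pancreas. At week 10, 11 were, against 0.918 by chance, and at week 12, 1 was, against 0.790. In the opposite direction, 2, 2 and 6 of the 110 were at least 2-fold lower at weeks 8, 10 and 12. At week 12, 38 of the 110 lay above 0, with a median log2 difference of -0.087. Reg3b, Reg3g, Mcpt1, Mcpt2, Cma2 and Cd53 were at least 2-fold higher at weeks 6, 8 and 10, although at week 10 a second probe set of Mcpt1, near the floor, gave a log2 difference of at least 0.19. Iigp1, Ubd, Socs1, an inhibitor of cytokine signalling, Mmp12 and Pea15a were so at weeks 6 and 10. Cd53 was the 1 gene higher at all 4 times. The chosen probe sets of Reg3b and Mcpt1 and the only probe set of Cma2 are marked for sequence shared with other genes. Cma2 may therefore not be independent of Mcpt1. Of the 43 genes lower at week 6, 5 were lower at week 8 (Ern2, Ltbp4, Rangrf, Sult1a1 and Tgm3), 0 at week 10 and 1 at week 12 (Mab21l2). These gene names were chosen after their values were seen. Without probe sets of shared sequence, an alternative added after seeing the data, 15 and 7 genes were higher again at weeks 8 and 10. This omission put the complement medians at weeks 6 and 10 (0.24 and 0.22) and the pancreas median at week 12 (-0.31) inside the random lists, and the collagen median at week 8 (0.22) and the stress median at week 10 (-0.20) outside. It also ended the matrix protease call on the interaction (adjusted p = 0.130 in limma's camera).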

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

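The list test of the difference between times was planned, while the tests that weigh explanations, the settings tried on it and each pool left out were chosen only after the result was seen. A test of the interaction picked out 8 lists whose TNBS effect was higher at week 6 than later. Week 6 has 1 TNBS pool and 1 saline pool, so the spread in this test comes from the 3 later TNBS pools alone. The neutrophil and acute inflammation list differed by a median log2 of at least 1.44 (adjusted p = 1.05e-07; adjusted p = 0.394 with an estimated correlation) and the macrophage list by 0.55 (adjusted p = 1.05e-07; adjusted p = 0.394 with an estimated correlation). The proliferation list differed by 0.68 (adjusted p = 1.05e-07) and the matrix protease list by 0.32 (adjusted p = 0.0230), both with an adjusted p of 0.461 with an estimated correlation. The interferon response list differed by 1.21 (adjusted p = 6.94e-06) and the collagen list by 0.35 (adjusted p = 0.00469), both with an adjusted p of 0.500 with an estimated correlation. The chemokine list differed by 0.67 (adjusted p = 0.00469) and the antigen presentation list by 0.46 (adjusted p = 0.000897), both with an adjusted p of 0.430 with an estimated correlation. The neutrophil call rested on 4 of its 9 genes, which passed the filter through the week 6 TNBS pool alone. They lay at the floor in all later pools and had no residual variance. Without genes of that kind its median was 0.18 and the call was lost (adjusted p = 0.158), while the other 7 lists passed. At the preset correlation, the chemokine (adjusted p = 0.0647), interferon (0.0717) and matrix protease (0.0879) calls were lost with a floor of 100, and the matrix protease call with a floor of 25 (0.0647). Without a filter on low genes the chemokine and interferon (0.216 each), antigen presentation (0.132) and collagen (0.261) calls were lost.

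The 3 week 6 arrays also stand apart from the 4 later arrays in the beta-actin ratio, though not in the Gapdh ratio. A high level of the later saline pool is argued against for the macrophage list, because the later TNBS pools differed from the week 6 saline pool by a median log2 of 0, against 0.95 at week 6. For the interferon list that median was 1.10 against 1.26 at week 6. The saline pools differed on this list by a median log2 of 0.96, the later pool being higher. A high level in the later saline pool, or a low level in the week 6 saline pool, may thus account for the interferon difference. These values, like the 0 of the macrophage list, cross the array sets. A difference between these array sets cannot be told apart from the time of the pools: 7 of the 8 lists lay at percentile 97.5 or above at week 6, but the same interaction had picked these lists, so this count excludes nothing. Time after the last enema remains open and cannot be told apart from differences between single pools, as each time is 1 pool. The camera test with an estimated correlation, with 0.394 as the smallest adjusted p, cannot decide it.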

How the results depend on the processing

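Each group is 1 pool, signals near the floor decide many counts, and the later comparisons share 1 saline pool. No paired analysis was possible because the pools hold different mice. Of 679 values of named genes under other settings, 518 stayed within the spread of the repeated arrays, 156 moved further and 5 turned. Of 368 list results on the pooled model, 312 kept their side of the threshold, 42 lost the call, 12 gained it and 2 turned. On the interaction, 278 of 305 kept their side, with 21 lost and 6 gained. Direction was compared only for lists called in the main setting, so turns of other lists are not counted. The list medians stayed within the spread of random lists in 155 of 185 cases at week 6, 116 of 164 at week 8, 130 of 164 at week 10 and 133 of 164 at week 12. The settings on the interaction lists, each later pool left out there, the omission of genes with no residual variance, that of probe sets of shared sequence and list medians under log2(value + 50) were chosen after seeing the data.

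Counts of genes at least 2-fold different moved by construction with the floor, which sets how far low signals can differ. With a floor of 25, higher and lower genes numbered 180 and 100 at week 6, 106 and 179 at week 8, 76 and 116 at week 10, 82 and 115 at week 12, and 65 and 106 between saline pools. Of the week 6 changes, 4 higher and 2 lower genes were shared at week 12. With a floor of 100 there were 72 and 27 at week 6, 27 lower at week 8, 22 and 8 at week 10, 10 and 17 at week 12, and 19 and 18 between saline pools. Then 3 lower genes were shared at week 8, 7 higher at week 10 and 0 lower at week 12, and 4 lists lay outside random lists at week 12. The same floor gave 69 genes in the late model and 188 in the interaction, of which 58 and 165 had no residual variance because their pools were tied at the floor. Without a filter the pooled model gave 17 genes, the late model 182 and the interaction 489, of which 158 of the late and 459 of the interaction genes had no residual variance, and 5 interaction lists passed. A filter at 300 left 5 interaction lists, with fewer genes tested.

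Under log2(value + 50), which shrinks low signals, counts were 68 and 21 at week 6, 21 lower at week 8, 15 and 7 at week 10, 17 and 17 at week 12, and 19 and 17 between saline pools. A 3-fold limit left 35 and 6 at week 6, 23 and 3 at week 8, 6 and 1 at week 10, 3 and 4 at week 12, and 6 and 4 between saline pools. For shared genes the limit was 3-fold at week 6 and stayed at 2-fold later. Then 15 higher and 0 lower genes were shared at week 8, and 0 lower at week 12. Equal medians, which shift all genes of an array alike, gave 116 and 32 at week 8, 66 and 17 at week 10, and a mitochondrial median of 0.029 at week 8, still at percentile 2.32 among random lists. For the following the cause was not tested. Quantile normalization gave 46 lower genes at week 8 and 2 shared lower genes there. The mean of probe sets gave 17 lower genes at week 10, and the limit against each saline array 23 lower genes between saline pools.

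With the week 6 saline pool as the control, counts were 142 and 139 at week 8, 77 and 68 at week 10, and 57 and 87 at week 12, and 7 lists lay outside at week 10. Medians turned to -0.052 (goblet) and 0.19 (mitochondrial) at week 8, -0.25 (complement) and 0.13 (colonocyte) at week 10, and 0.29 (interferon), 0.057 (colonocyte) and 0.084 (stress) at week 12. Log2 differences turned to -1.21 for Rpl41 at week 8 and to -1.27 for Limk1, 0.53 for Isg15 and at least 0.19 for Usp18 at week 12. Without the control-set covariate 6 pooled lists passed, and with an estimated correlation 0 pooled and 0 interaction lists passed in limma's camera. Without probe sets of shared sequence, 27 genes were lower between saline pools, 15 and 7 higher genes were shared at weeks 8 and 10, and Igfbp4 was at -0.25 at week 10.

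Leaving out single arrays or pools gave 50 to 64 lower genes between saline pools, 0 to 2 pooled genes and 0 to 12 pooled lists. The pooled interferon median ranged from -0.011 to 1.26. The 2 genes came without the week 12 TNBS pool. The lowest list counts came when the week 6 TNBS pool or the week 6 saline pool was left out. Leaving out either takes the week 6 comparison out of the pooled model, since the control-set covariate absorbs the other. The pooled list calls thus depended on the week 6 comparison. For array data, signal over background limits what can be read: 45.4% to 49.2% of probe sets were under the floor.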

Other observations

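The genes of this paragraph were chosen after their values were seen. Isg15, a ubiquitin-like protein induced by type I interferon, had signals of 193 and 176 on the week 6 saline arrays, 302 in the week 6 TNBS pool, 695 in the later saline pool, and 1194, 445 and 267 in the week 8, week 10 and week 12 TNBS pools. Usp18, its protease, had signals below the floor on both week 6 saline arrays, 142 in the later saline pool and 281 in the week 8 TNBS pool. Ifit1, which binds foreign RNA, was also below the floor on the week 6 saline arrays and read 256 in the later saline pool. At week 8 the endoplasmic reticulum chaperones Hspa5 and Hsp90b1 were 1.91-fold and 2.05-fold higher, and the haemoglobin genes Hba-a1 and Hbb-b2 2.04-fold and 3.79-fold higher. At week 12 these haemoglobin genes were 2.15-fold and 1.74-fold lower. Scd1, a fatty acid desaturase of adipose tissue and other cells, was 2.52-fold higher at week 8. Rpl41 read 4600, 2162 and 1080 in the week 8, week 10 and week 12 pools, 1109 in the later saline pool and at least 9879 on the 3 week 6 arrays.

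All the tests in the next 2 paragraphs were chosen only after the result was seen. Pancreatic enzyme genes were higher in the week 6 and week 8 TNBS pools, and pancreatic tissue or RNA in the pooled pieces is a candidate explanation. The pancreas list was fixed beforehand, and 4 of its 9 measured genes averaged a signal of at least 100 in the saline pools. Of its 7 genes under 300 in saline, 6 were at least 2-fold higher in both pools, with Ctrl at week 6 (log2 0.77) the exception, while Clps, abundant in pancreas, read 506 at week 6 against 592 and 455 in saline. Shared probe sequence is argued against, since the list's median was 2.63 at week 8 without such probe sets. TNBS and the time after it remain open, with a list median of -0.11 at week 10 and 1 pool per time.

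Reg3b, Reg3g, Mcpt1 and Mcpt2 were higher through week 10 and not at week 12, with Mcpt1 at a log2 difference of at least 0.19 at week 10 on a second probe set near the floor. Pancreatic tissue, which also expresses Reg genes, is argued against at week 10, where 0 of the 7 low-level pancreas genes were at least 2-fold higher. Shared probe sequence remains open for Reg3b and Mcpt1, whose probe sets carry that mark. The chosen probe sets of Reg3g and Mcpt2 do not, which argues against it for these genes alone. Their log2 differences of 1.88 and 2.06 at week 10 are part of the pattern itself and add no test. The time after the last enema may set the end of this pattern, as Reg3b was at -0.92 at week 12. That explanation cannot be told apart from differences between single pools, as each time is 1 pool and week 12 has no saline pool of its age.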
